A study of Mus musculus with 12 samples.

How the data were processed

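Liver RNA of 12 male ApoEshl mice was labelled from 10 micrograms of total RNA each and hybridised to a focused cDNA array, per the labels' protocols. Groups were taken from the sample labels, 6 mice on the high-fat diet (HFD) and 6 on that diet with 5% fucoidan, with replicate numbers in the order of the sample titles. Per the file headers, the slide was scanned at 532 nm on a GenePix scanner (model 4000B) and quantified with GenePix Pro 6.0.1.27 with a local background for each spot. The deposited raw table gives intensity on a linear scale, as foreground, local background and listed difference, with no scaling between arrays. What was done to the table after quantification is not given in the sources used here. Each mouse occupies a pair of blocks on 1 slide image. All 12 raw columns were used, and 0 columns of samples were left unused.

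The array lists 396 spots in 2 sets of 198, with 354 spots of named genes, 25 empty spots, 1 closed spot and 16 spots of 4 negative control sequences. Of 331 names in the file, 315 were current mouse symbols in the reference table, 15 were matched through a single synonym, and 1 had several synonyms and was kept as listed. This gave 330 genes, of which 7 had more than 1 spot. The deposited value table of the series also holds intensity on a linear scale, from −27 to 50344 with 597 values below 0, and what the authors did to make it is not given in the sources used here. Its 354 rows carry no gene names, and 0 of them lay within 1 of any spot's listed difference on all 12 arrays, so its rows were not named and it served only as an alternative count. The column medians of the value table were 139.5, 116, 132, 129.5, 121 and 113.5 for HFD replicates 1 to 6 and 171, 155, 126, 102.5, 119 and 135 for fucoidan replicates 1 to 6. Its scale factor and normalisation stay unknown.

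Every spot was checked with scripts in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, figures with matplotlib 3.10.9) for whether the listed difference was foreground minus background within 0.5, whether the foreground exceeded the 16-bit maximum of 65535, and whether a value was missing. 41 gene spots failed, and they were kept in the planned fit, with a fit without them added. A wider set of 53 gene spots adds those that share their background on all 12 arrays with another spot.

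Intensities were background corrected in R 4.3.3 with limma 3.58.1 (normexp, offset 50), quantile normalised over the 354 gene spots and expressed as log2. Spots of a probe were averaged, then probes of a gene. A gene was above the detection limit on an array when its foreground exceeded the mean plus 2 SD of the 41 negative control and empty spots of that array, and genes above it on at least 6 of the 12 arrays were tested, which left 181 genes, 158 of them above it on all 12, and 149 not tested. Differences are log2 values of fucoidan minus HFD from limma (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Gene lists with at least 3 tested members were tested with fry (statmod 1.5.0), adjusted over the 15 lists. The offset and the quantile normalisation draw differences of dim genes towards 0.

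The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names the 12 highest and 12 lowest genes by log2 fold change past the threshold, the genes of smallest p up to 20 where fewer pass, 14 genes of lipid and glucose metabolism wherever measured, and the 3 members of largest change of each list tested. Of those, Srebf2 and Pck1 are not among the names on this array. Some genes that the rule takes are not reported here, though they stay in every count of genes and lists. Genes named as the remaining members of a list with few tested members, such as Abca1 and Fabp4, and Mttp as 1 of 3 that passed over its list alone, fall outside the rule and were named after their values were seen.

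The alternatives were other background corrections, normalisations, detection filters, priors, array weights, an exact permutation test, a threshold of 0.1, the replicate number as a block, camera in place of fry, the value table, and leaving out each array. Slide, scan and block position could not be fitted, because all arrays share 1 slide and each has its own blocks. On simulated tables with 181 genes, the pipeline recovered 0.638 of genes changed by 0.5 log2 units and 0.9 of those changed by 1, with 0.102 of calls false. With the 147 genes left without the failed spots it recovered 0.768 and 0.963, with 0.158 of calls false. The share of false calls exceeded the threshold of 0.05 in both simulations. The noise in both was taken from normalised values and then normalised again, so the shares recovered can be too high for dim genes. A list shifted by 0.5 was recovered by fry in 20 of 20 tables, with 2 of 260 other lists called.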

Results

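Liver RNA was measured in 12 male ApoEshl mice, a line that carries a spontaneous defect of Apoe, the gene of apolipoprotein E, which clears remnant lipoproteins from the blood. The labels give an age of 7 to 8 weeks and 12 weeks of diet. The mice fall into 6 that ate a high-fat diet (HFD group) and 6 that ate the same diet with 5% fucoidan, a sulphated polysaccharide of brown seaweed (fucoidan group). Each mouse was hybridised alone, in 1 colour, to a focused array of 330 genes of lipid and carbohydrate metabolism, insulin signalling and inflammation. The normal diet and the lower fucoidan dose that the protocol names were not analysed here. The number of arrays limits the precision, and the p-values of the group comparisons measure the spread between these mice.

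Array brightness was similar in both groups. The median spot foreground was 195 ± 25.2 in the HFD group and 196 ± 20.4 in the fucoidan group (SD, n = 6 each, two-sided exact permutation p = 0.987), with array medians from 168 to 232. Between 195 and 210 of the 354 gene spots were above the detection limit in the HFD group, and between 199 and 209 in the fucoidan group (exact permutation p = 0.703). The arrays correlated with one another at 0.902 to 0.985 across genes, which are not independent replicates, and no array was a copy of another. All HFD arrays lay in blocks 1 to 12 of 1 slide and all fucoidan arrays in blocks 13 to 24, so position on the slide and group cannot be told apart.

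The raw table lists a foreground, a local background and their difference for every spot. On 41 gene spots, each of a different gene, the listed difference was not foreground minus background within 0.5 on at least 1 array, which came to 422 of 4751 cells compared. 27 of these spots failed on all 12 arrays, 5 cells held a foreground above 65535, the largest number a 16-bit scanner returns, and no control or empty spot failed. The median distance between listed and computed difference in the failing cells was 80. These 41 are called the failed spots, and each gene below that rests on one is named as such.

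Apoe, the gene that is defective in every mouse here, stood above the detection limit on all 12 arrays. Its normalised log2 intensity was 8.86 ± 0.59 in the HFD group and 8.51 ± 0.34 in the fucoidan group (SD, n = 6 each). The difference of −0.35 (SE 0.26) did not pass the limma test (adjusted p = 0.457). The file does not give the part of the transcript the Apoe probe binds, so this level does not check the defect, and both groups carry it.

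The comparison of the groups asks which genes of lipid and carbohydrate metabolism fucoidan changes in the liver of mice on a high-fat diet. In the fucoidan group the 2 bile acid enzymes listed for the array were the most reduced genes. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 2.51 on the log2 scale (SE 0.41) and Cyp8b1, the sterol 12-alpha-hydroxylase that makes cholic acid, fell by 2.61 (SE 0.41). Socs3, an inhibitor of cytokine and insulin signalling, fell by 1.54 (SE 0.14), and Jun, a subunit of the AP-1 transcription factor, rose by 1.54 (SE 0.22). The spots of all 4 of these genes were failed spots. Those of Cyp7a1 and Cyp8b1 each held 1 foreground above 65535. Without HFD replicate 1 the log2 fold change was −2.09 for Cyp7a1 and −2.19 for Cyp8b1. On a spot that passed, Acsl1, which activates long-chain fatty acids, rose by 0.69 (SE 0.15).

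In all, 181 of the 330 genes were above the detection limit on at least 6 arrays and were tested, 15 passed an adjusted p of 0.05 in limma, and 40 had an unadjusted p under 0.05. Of the 15, 7 rose and 8 fell with fucoidan. Failed spots carried 34 of the 181 genes tested, but 10 of the 15 that passed, including all 8 that fell (two-sided Fisher's exact p = 2.45e-05). The other 5 rested on spots that passed the checks and all rose. The median size of the log2 fold change was 0.55 for genes on failed spots and 0.12 for the others. The median SE was 0.12 over all 181 genes tested, and was not taken separately for genes on failed spots. With the failed spots left out, a choice made after seeing the data, 147 genes were tested in limma and 0 passed, with a smallest adjusted p of 0.207 and 15 at an unadjusted p under 0.05. An exact permutation test per gene likewise gave 0 of those genes after adjustment and 15 before it.

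Among the genes that fell, all on failed spots, the adjusted p was 1.85e-05 for Socs3, 4.52e-05 for Ffar1, 0.0015 for Cyp8b1 and 0.00162 for Cyp7a1. Ffar1, a receptor for long-chain fatty acids, went from 13.96 ± 0.24 to 12.86 ± 0.16 (SD, n = 6 each), lower in 6 of 6 mice than the HFD mean. Cfd, complement factor D, fell by 0.60 (SE 0.12, adjusted p = 0.00603). Cdkn1a, an inhibitor of the cell cycle, fell by 2.07 (SE 0.54, adjusted p = 0.0317), with an HFD mean that held 1 array at 14.94 while the median of the other 5 was 11.48. Hsd11b1, which regenerates active glucocorticoid, fell by 0.91 (SE 0.24, adjusted p = 0.0317) and was lower in 5 of 6 mice. Leaving out single arrays ended the call of Hsd11b1 in 8 of 12 fits and that of Cdkn1a in 6. Cyp7a1 and Cyp8b1 have neighbouring spots whose listed foregrounds were identical on 11 of 12 arrays and whose backgrounds and listed differences were identical on all 12, so the pair is 1 measurement as listed. Both spots also shared their background on all 12 arrays with a passed spot of another gene.

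Among the genes that rose, Jun, on a failed spot, had an adjusted p of 7.65e-04 and a higher value in 6 of 6 mice. The Jun spot listed the same background as an Rps18 spot on all 12 arrays and the same foreground on 3. Acsl1 went from 11.68 ± 0.19 to 12.37 ± 0.33 (SD, n = 6 each), which was 1.61 times the HFD level, with a limma adjusted p of 0.0122 and a higher value in 6 of 6 mice. Igfbp1, a secreted binding protein of insulin-like growth factors, rose by 0.80 (SE 0.19, adjusted p = 0.0246), in 5 of 6 mice. Gapdh, a glycolytic enzyme often used as a reference gene, rose by 0.41 (SE 0.10, adjusted p = 0.0317). Gk, glycerol kinase, rose by 0.31 (SE 0.09, adjusted p = 0.0454). When the failed spots were left out before normalisation, the fold change of Acsl1 was 0.42, of Igfbp1 0.60, of Gk 0.30 and of Gapdh 0.07, with adjusted p from 0.207 to 0.652. With all spots kept, 0 of the 5 genes on passed spots passed when arrays were scaled to the housekeeping genes or not normalised between arrays. Acsl1 then had 0.41 (adjusted p = 0.0964) and 0.62 (adjusted p = 0.0849), and in an exact permutation test per gene its adjusted p was 0.0557. The Igfbp1 spot and a Gapdh spot also shared their background on all 12 arrays with a failed spot, that of Hsd11b1 for Igfbp1 and that of Acss2 for Gapdh.

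**Figure D1:**
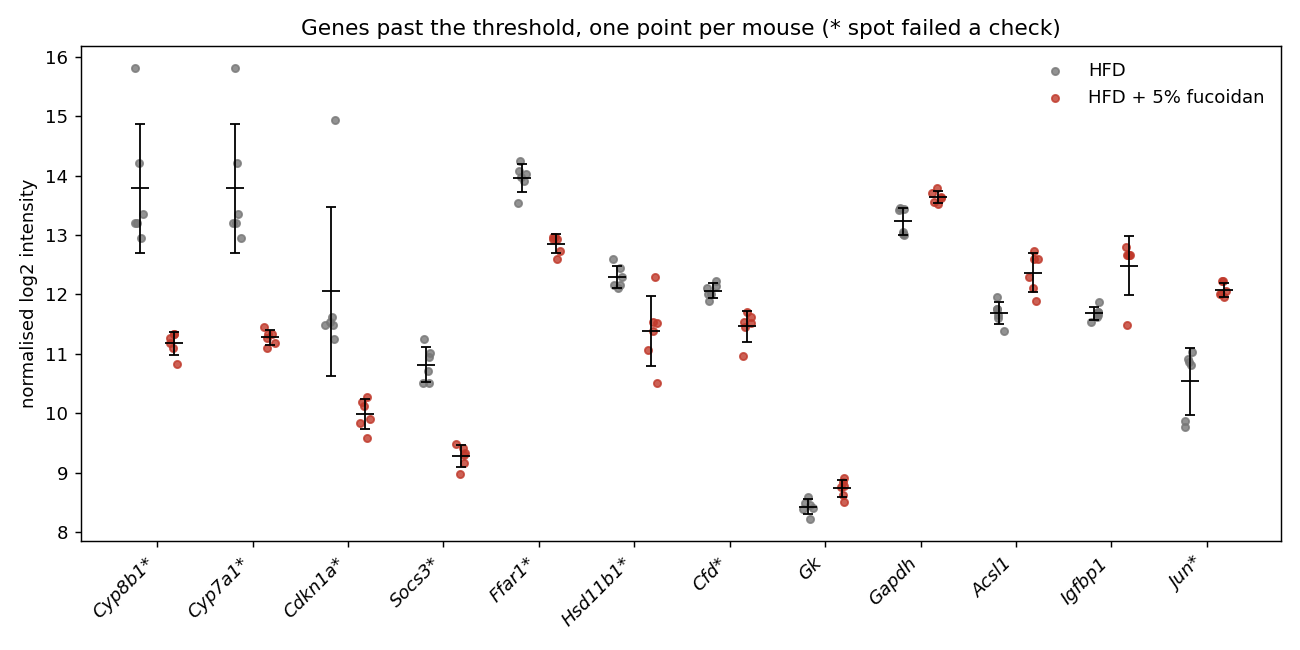
Normalised log2 intensity of 12 genes that passed an adjusted p of 0.05, 1 point per mouse, with the group mean and SD as bars, HFD in grey and HFD with 5% fucoidan in red. Genes with an asterisk rest on failed spots, which include all 7 genes drawn that fell, and the HFD points of Cyp7a1 and Cyp8b1 coincide.

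The next 5 genes by p did not pass. Apoa1, the main protein of high-density lipoprotein, had a log2 fold change of 0.62 (SE 0.19, adjusted p = 0.0636), and Apoa2 one of 0.25 (adjusted p = 0.0825). Acat2, a thiolase of cholesterol synthesis, had −1.02 (adjusted p = 0.0701), Srebf1, the transcription factor of fatty acid synthesis, had −0.60 (adjusted p = 0.0825), and G6pc, the last enzyme of glucose release, had −0.49 (adjusted p = 0.0835), all 3 on failed spots. Apoa1 and Apoa2 turned to −0.02 and −0.09 when arrays were scaled to the housekeeping genes, and without the failed spots Apoa1 had 0.12 (adjusted p = 0.599) and Apoa2 −0.13. None of the following genes passed. Lpl, which hydrolyses circulating triglyceride, had −0.18 (95% interval −0.57 to 0.20) and the fatty acid synthase Fasn −0.12 (−0.76 to 0.52). Cpt1a, which admits fatty acids to mitochondria, had 0.10 (−0.09 to 0.30), while Ppara, the receptor that drives fatty acid oxidation, had 0.28 (−0.52 to 1.08) on a failed spot, or 0.04 without fucoidan replicate 3 and 0.56 without HFD replicate 3. These intervals do not exclude changes in either direction.

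**Figure D2:**
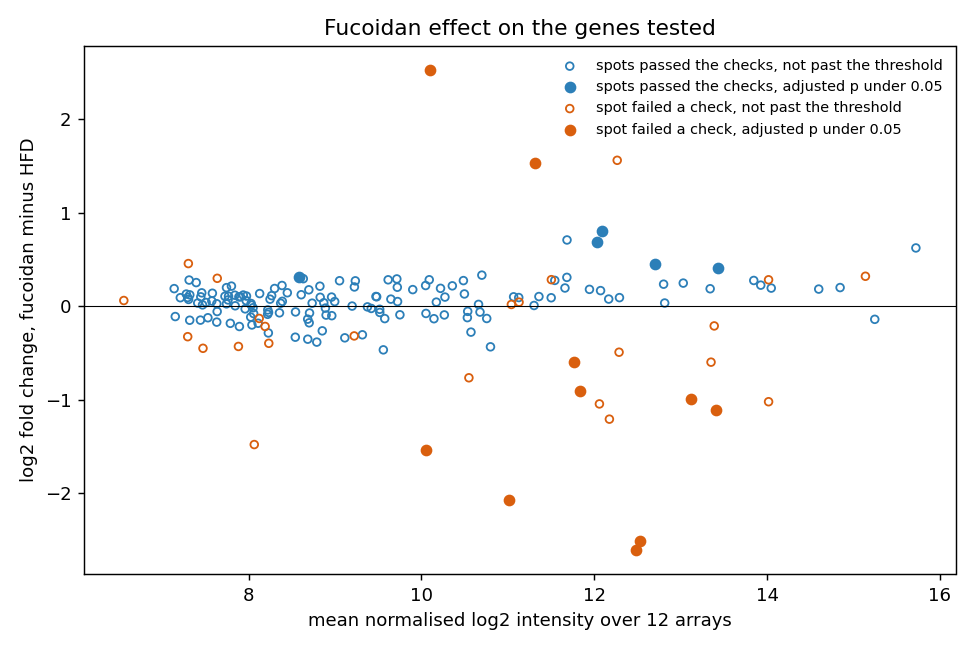
Log2 fold change of fucoidan over HFD (vertical axis) against mean normalised log2 intensity over 12 arrays (horizontal axis) for the 181 genes tested, filled where the adjusted p was under 0.05. The 34 genes on failed spots, in orange, have a median size of 0.55 and the 147 others, in blue, of 0.12.

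Of 25 gene lists fixed for this tissue and treatment, 15 had at least 3 tested members, and 4 passed fry, limma's test of whether a list's genes move on balance one way. The list of bile acid synthesis and sterol transport fell (adjusted p = 0.014). In camera, which compares a list with the other genes, it passed with a preset correlation (adjusted p = 0.0121) but not otherwise (adjusted p = 0.466 with an estimated correlation). It had 2 of its 4 tested members past the threshold over all genes and 3 when adjusted over the list alone, but these count the values of Cyp7a1 and Cyp8b1, which are 1 measurement as listed, as 2. With the pair averaged to 1 member, a choice made after seeing the data, the list of 3 members, 2 of them on failed spots, passed fry (adjusted p = 0.0371) and not camera with a preset correlation (adjusted p = 0.12). Beside Cyp7a1 and Cyp8b1, its members were Nr5a2, a nuclear receptor that activates both, at −0.22 (SE 0.09), and Abca1, a cholesterol exporter, and 3 of the 4 rested on failed spots. Fatty acid synthesis fell as a list (adjusted p = 0.0371), but not in camera (adjusted p = 0.466 with an estimated correlation), and it lost its call in 8 of the 12 fits that left out 1 array (adjusted p up to 0.127). It had 5 of 6 members lower, 0 past the threshold over all genes and 2 when adjusted over the list alone. Its largest values were −1.05 (SE 0.37) for Acly, which makes acetyl-CoA for lipid synthesis, and −0.60 for Srebf1, both on failed spots, and 0.28 (SE 0.37) for malic enzyme Me1, on a passed spot, or −0.05 without HFD replicate 5. With the failed spots left out, its 3 remaining members had a mean of 0.01 and a test that leaned down (adjusted p = 0.977), and the bile acid list kept 1 member, too few for a test.

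The list of hepatocyte markers rose (adjusted p = 0.00387), but not in camera (adjusted p = 0.466 with an estimated correlation), with 0 of 5 members past the threshold over all genes and 2 when adjusted over the list alone. Its largest values were those of Apoa1 and Apoa2 and 0.30 (SE 0.44) for the liver transcription factor Hnf4a, on a failed spot, or −0.15 without fucoidan replicate 6. The housekeeping list also rose (adjusted p = 0.0189), though not without HFD replicate 3 (adjusted p = 0.0506). In camera it passed with a preset correlation (adjusted p = 0.0413) but not otherwise (adjusted p = 0.466 with an estimated correlation). It had 8 of 8 members higher and 1 past the threshold, both over all genes and when adjusted over the list alone. Its examples were Gapdh, the translation factor Eef1a1 at 0.28 (SE 0.11) and the beta-2-microglobulin gene B2m at 0.20 (SE 0.13). Both lists lost their call without the failed spots, at adjusted p = 0.977 for hepatocyte markers and 0.503 for housekeeping. Their test turned down when arrays were scaled to the housekeeping genes. That scaling sets the mean of the housekeeping list to 0 by construction, so it is no test of that list's rise. It also moved the median of all genes tested from 0.05 to −0.12.

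**Figure D3:**
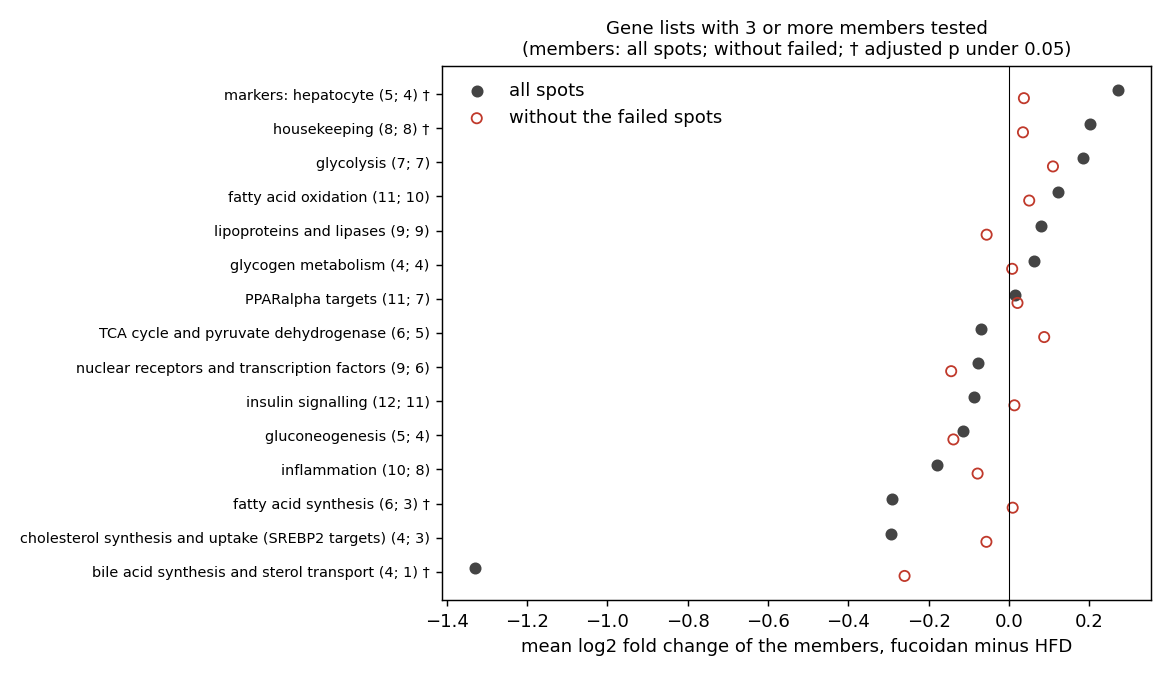
Mean log2 fold change of fucoidan over HFD for the tested members of 15 gene lists, with all spots (filled) and without the failed spots (open), and the number of members under each in brackets. Daggers mark the 4 lists with an adjusted p under 0.05 with all spots, and 0 of the 14 lists that could be tested without the failed spots passed.

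The insulin signalling list did not pass for 1 direction (adjusted p = 0.0753) but did for changes in either direction (adjusted p = 2.44e-07). Of its 12 tested members, 1 rose and 1 fell, namely Igfbp1 and Socs3, the same 2 that passed when adjusted over the list alone, and the kinase subunit Pik3r1 had 0.27 (SE 0.25), or 0.06 without fucoidan replicate 2. Lipoproteins and lipases likewise passed only for either direction (adjusted p = 0.00958, against 0.118 for 1 direction), with 0 of 9 members past the threshold over all genes and 3 when adjusted over the list alone, Apoa1, Apoa2 and Mttp, which loads lipid onto apolipoprotein B. Inflammation did so too (adjusted p = 0.00958, against 0.0696), where 1 of 10 members was past the threshold by either adjustment, the chemokine Ccl2 had −0.77 (SE 0.63) on a failed spot, or −0.11 without HFD replicate 5, and the kinase Mapk8 0.71 (SE 0.29). The Mapk8 spot listed the same background as an Rps18 spot on all 12 arrays and the same foreground on 8. None of these 3 lists passed for either direction without the failed spots (adjusted p = 0.484 each).

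The remaining 8 lists did not pass in either form of the test. Fatty acid oxidation (adjusted p = 0.183) had Acsl1 as its 1 of 11 members past the threshold by either adjustment, with 0.31 (SE 0.17) for Hsd17b10 and 0.22 (SE 0.19) for Ehhadh. The PPARalpha target list (adjusted p = 0.366) had 1 of 11 past the threshold, with −1.21 (SE 0.63) for the pyruvate dehydrogenase kinase Pdk4 and 0.32 (SE 0.15) for the fatty acid binding protein Fabp1, both on failed spots, and 1 when adjusted over the list alone. Without HFD replicate 3 the value of Pdk4 was −0.53, and with the listed differences it was −0.59. Glycolysis (adjusted p = 0.0753) had Gapdh as its 1 of 7 by either adjustment, with 0.27 (SE 0.16) for the glucose transporter Slc2a2 and 0.21 (SE 0.22) for Pklr. Cholesterol synthesis and uptake (adjusted p = 0.168) had 0 of 4 past the threshold and 1 when adjusted over the list alone, with 0.29 (SE 0.36) for Insig2, or 0.06 without fucoidan replicate 2, and −0.26 (SE 0.21) for Insig1, or −0.11 without HFD replicate 5. Gluconeogenesis (adjusted p = 0.142) had 0 of 5 and 1 when adjusted over the list alone, with 0.19 (SE 0.12) for Fbp1 and −0.17 (SE 0.11) for Foxo1 beside G6pc.

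Glycogen metabolism (adjusted p = 0.446) had 0 of 4 by either adjustment, with 0.22 for Gys2, 0.10 for Pygl and −0.10 for Gsk3b. With single arrays left out, Gys2 ranged from 0.12 to 0.37, Pygl from 0.03 to 0.16 and Gsk3b from −0.18 to −0.05. The list of the TCA cycle and pyruvate dehydrogenase (adjusted p = 0.281) had 0 of 6 by either adjustment, with 0.28 for Mdh1 and 0.20 for Dld. Its median was 0.13 and its test leaned up, while its mean of −0.07 was set by Pdk4. Nuclear receptors and transcription factors (adjusted p = 0.366) had 0 of 9 by either adjustment, with −0.43 (SE 0.26) for Cebpb, or −0.24 without HFD replicate 1, beside Srebf1 and Hnf4a.

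Markers of cells other than hepatocytes were mostly below the detection limit. Of 11 adipocyte markers on the array 2 were tested, with Cfd, also made in liver, lower on its failed spot and Fabp4 at 0.03. Of 3 markers of macrophages and other leukocytes 2 were tested, Cd36 at −0.07 and Ccl2, of 6 pancreas and gut markers 1, Fabp2 at 0.28, and of 2 stellate and endothelial markers 1, Nos3 at −0.45 on a failed spot, none of which passed. None of the 6 muscle markers was tested. Other lists with fewer than 3 tested members were ketone body metabolism (Acat1 at 0.33, past the threshold when adjusted over the list alone), triglyceride synthesis and storage (Pnpla2 at −0.29), oxidative stress defence (Hmox1 at −0.47) and mitochondrial respiration (Ucp2 at −0.03). Leaving out 1 array turned the sign of several of these values. Nos3 had 0.13 without HFD replicate 1 and Pnpla2 0.01 without HFD replicate 6, and the small values of Fabp4, Cd36 and Ucp2 also took either sign. The pentose phosphate list had 0 tested members.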

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

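The tests of the failed spots and of the rise in the hepatocyte marker and housekeeping lists were chosen after these results were seen, while the count over other splits was planned. Of 100 groups of 6 values examined, 13 held a sample far from the other 5, where chance gives about 5. Failed spots held 7 of these among 34 groups, and the other spots and array measures 6 among 66. Among genes past the threshold, fucoidan replicate 2 was low for Igfbp1 at 11.48, HFD replicate 1 was high for Cdkn1a at 14.94, and fucoidan replicate 3 was low for Cfd at 10.97. For Apoa1, HFD replicate 4 was high at 16.15 and fucoidan replicate 1 low at 15.47. These are the values that the normalisation gives to ranks 1 and 2 of an array. A failed spot held rank 1 in fucoidan replicate 1, and Apoa1 tied at rank 1 on the other 5 fucoidan arrays. The number expected by chance therefore does not apply to that group. High values in the HFD group on failed spots were Acat2 at 16.15 in replicate 6, Ppara at 12.73 in replicate 3, Pdk4 at 16.15 in replicate 3 and Ccl2 at 14.25 in replicate 5. Fucoidan replicate 6 was low for Me1 at 9.51, and high for Hnf4a at 10.03. HFD replicate 6 was high for Pik3r1 at 9.59, and HFD replicate 3 for Mapk8 at 12.01.

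Cyp7a1, Cyp8b1, Socs3 and 7 further genes past the threshold rested on failed spots, and without those spots 0 of 147 genes passed. Chance is an unlikely source of the count of 15 genes but is not excluded. Only 1 of 100 splits of the 12 arrays, the real one, gave as many, and the highest other split gave 4. That share is the smallest these splits can give. With all spots kept, the limma test called 5 genes whose spots passed. With the failed spots left out it called 0 of 147 genes. In that second setting, simulated changes of 1 log2 unit were recovered in a share of 0.963. If the noise is as simulated, this argues against a fucoidan effect of that size on many of these genes. The simulation changed 20 genes by 1 and 20 by 0.5, with independent noise, so it does not cover an effect on a few genes. Its noise was taken from normalised values and then normalised again, so the share recovered can be too high for dim genes. A candidate explanation for the failed spots is listed values that do not belong to the spot's own place on the slide: their local background lay a median of 5.5 from that of the neighbouring spots against 1.5 for other gene spots, a difference of 4 (permutation p = 1e-05, the smallest the resamples can give). What made these values differ is not known, and an effect of fucoidan on Cyp7a1, Cyp8b1, Socs3 and the other genes themselves stays open and was not tested, because no other spot measures them.

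The lists of hepatocyte markers and housekeeping genes rose with fucoidan in fry on the quantile-normalised values, though not in camera (adjusted p = 0.466 with an estimated correlation), and of their members Gapdh alone passed over all genes. Ranks displaced by the failed spots may account for part of this: Apoa1 was the brightest gene on 5 of 6 fucoidan arrays but on 1 of 6 HFD arrays, where a failed spot was brightest on 4, and without the failed spots the mean of the 12 members on passed spots went from 0.22 to 0.04, a ratio of 0.159. In values that exchange no ranks, the mean was 0.19 both with median centring (exact permutation p = 0.0433) and with no normalisation (exact permutation p = 0.232), against medians of 0.10 and 0.09 over all genes tested, and neither list passed fry in either. An effect of fucoidan on these genes also stays open, since the smaller unadjusted p of the lists in fry was 0.159 without the failed spots. The explanations cannot be told apart. Quantile normalisation over the passed spots alone can also draw a shared rise of bright genes towards 0, so the ratio does not separate them. The shift without rank exchange passed 0.05 under 1 of these scalings and not under the other.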

How the results depend on the processing

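Leaving out the failed spots, or these and the spots that share backgrounds, using the listed differences and averaging Cyp7a1 and Cyp8b1 were chosen after seeing the data. From 15, the count of genes past the threshold went to 0 in both fits without such spots (of 147 and 140 genes, with 15 and 14 at an unadjusted p under 0.05 in limma), 25 with the listed differences, 40 of 354 in the deposited value table, 27 at a threshold of 0.1, 9 with the replicate block, and 9 to 17 when single arrays were left out, with 9 without HFD replicate 3 and without HFD replicate 5. Of the 15 named genes that passed, 9 did so with the replicate block, 9 in the exact permutation test (11 genes in all, 42 unadjusted), 0 in both fits without failed spots, and 9 to 15 with single arrays left out. Cyp7a1, Cyp8b1, Socs3, Ffar1, Cfd and Jun passed in all 25 alternatives that kept their failed spots. Leaving out single arrays ended the calls of Gk in 9 of 12 fits, Hsd11b1 in 8, Igfbp1 and Cdkn1a in 6 each and Gapdh in 5, always including HFD replicates 3 and 5. The replicate numbers do not pair the mice: 2 of 6 same-numbered pairs had a correlation above 0.1 (−0.24 to 0.16), and 1 of 6 HFD arrays and 1 of 6 fucoidan arrays correlated best with their own number. The split of 7 higher and 8 lower became 5 and 10 with median centring, 2 and 10 with housekeeping scaling or no normalisation, and 3 and 8 with plain subtraction. Housekeeping scaling moved the median log2 fold change of all genes tested from 0.05 to −0.12. The 4 lists past the threshold became 0 with median centring, housekeeping scaling, no normalisation, camera with an estimated correlation and both fits without failed spots, 2 with camera's preset correlation, 7 at a threshold of 0.1, 4 with Cyp7a1 and Cyp8b1 averaged, and 2 to 8 with single arrays left out (2 without HFD replicate 3, 8 without HFD replicate 4, 7 without HFD replicate 6). The Apoe level of 8.69 became 8.19 with plain subtraction, which removes the offset. Housekeeping scaling, which sets the mean of that list to 0 by construction, turned the direction of the hepatocyte list (adjusted p = 0.596) and the housekeeping list (0.76), of Apoa1 (−0.017), Apoa2 (−0.088), Cpt1a (−0.073), Fbp1 (−0.18), Pygl (−0.0083), Eef1a1 (−0.094) and B2m (−0.11). Without the failed spots, and without these and the spots that share backgrounds, Apoa2 turned to −0.13 and −0.12, Fbp1 to −0.20 and −0.21, Pygl to −0.026 and −0.036 and Eef1a1 to −0.026 in both. With single arrays left out, Fasn ranged from −0.24 to 0.090 (above 0 without HFD replicate 5 and without fucoidan replicate 4), Hnf4a from −0.15 to 0.42 (turned without fucoidan replicate 6), and Me1 from −0.052 to 0.46 (turned without HFD replicate 5). The cause was not tested where none is given. Slide, scan or well as a block was not run. Signal near background limits the 149 genes that were not tested.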

Other observations

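On passed spots, the number of genes at an unadjusted limma p under 0.05 lay within the range of other splits of the arrays. The real split gave 15. Most other splits gave fewer, but several gave more, up to 31. The genes below therefore do not stand out from what other groupings of these arrays give. Without the failed spots, the smallest adjusted p in limma, 0.207, was shared by Gk at 0.30 (SE 0.08) and Acat3, a thiolase, at −0.32 (SE 0.09). Enpp1, an inhibitor of insulin receptor signalling, had 0.24 (SE 0.08), Tnfrsf1a, a receptor of tumour necrosis factor, −0.37 (SE 0.14), and Mttp 0.21 (SE 0.08), each at an adjusted p of 0.277. None passed, and these genes were chosen after their values were seen.

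14 pairs of spots, made of 25 spots, listed the same local background on all 12 arrays, where 100 shuffles of the backgrounds within arrays gave 0 such pairs. In 11 of these pairs exactly 1 of the spots had failed the arithmetic check, and in 10 of the 11 the failed spot's background lay further from those of its own neighbours than its partner's did. The exception was the failed spot of Hsd11b1, at a median of 1.0 from its neighbours, and its partner Igfbp1, at 2.75. Over all failed spots, the median correlation of the background with the neighbours' across arrays was 0.795, against 0.958 for other gene spots. The largest listed foreground was 233426, on a failed spot, and the largest on a passed spot was 60613. 11 differences were listed with decimals, beside whole numbers elsewhere. The count of gene lists past the threshold was 4. Only 1 of 100 splits of the 12 arrays, the real one, reached it, and the highest other split gave 2. That share is the smallest these splits can give, so chance is an unlikely source of the count but is not excluded. It covers the main fit only, since no list passed with median centring, housekeeping scaling or no normalisation.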
